A study of Homo sapiens with 18 samples.

How the data were processed

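Total RNA of 18 libraries was measured: 6 primary fibroblast lines, each under DMSO control, TGFβ, and TGFβ with artesunate. RNA was taken up in Trizol and cleaned with a Qiagen kit, per the labels' protocols. The authors trimmed reads with Trim Galore, aligned them with STAR to hg38 and counted them per gene with featureCounts, per the submitters' processing notes; versions are not given in the sources used here. The deposited table holds TPM (reads over gene length, scaled to a common total) per gene symbol and library, computed by the authors, and every library has the same total over the listed genes. The annotation release, the gene lengths behind the TPM and the use of strand are not given in the sources used here. Genes are identified by symbol, since the table holds no other identifier, and coordinates were taken from GENCODE release 29 on GRCh38/hg38.

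Libraries were assigned to lines and treatments from their labels, and the line number used in the text stands for the label's letter. The assignment was checked on expression: the library of another treatment closest to each library was of its own line in 18 of 18 cases, with correlations of deviations from the treatment means from 0.5 to 0.77 within lines. No 2 libraries of a group were copies of each other, the lowest median chi-square per gene being 6.3. A gene was tested where it had at least 1 TPM in at least 6 of the 18 libraries, which left 17462 genes. X-inactivation and Y-linked genes were left out of all tests.

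The deposited values are TPM and not counts, so the depth was recovered from them. A read unit was sought for each library and a length for each gene, taken from the reference or else searched for, that turn the gene's values into whole reads within a tolerance of 0.02. They were found for 99.96% of the 17064 genes with a mean of at least 1 TPM, and these genes held at least 99.96% of the TPM of every library. Of the genes with few reads used to set the scale, 86.8% had a length that matches the reference annotation. On data simulated with the read units already found, the search for gene lengths returned the reads of 300 of 300 genes exactly. The finding of the read units, which set the depth, was not tested by this simulation. The recovered depth ran from 17.12 to 53.71 M reads per library and follows the numbering series of the labels, 3 lines each.

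The main test was limma with an intensity trend on log2(TPM + 1), with the line as a block and all 18 libraries in one fit, and a Benjamini-Hochberg adjusted p under 0.05 called a gene changed. Reported SE values are those of the fit and n is 6 lines. All tests were two-sided. The median SE over tested genes was 0.148. Tested on simulated data of the same libraries, the fit recovered 51.5% of genes changed by 0.5 on the log2 scale, 83.6% at 1 and 98.5% at 2, with 9 false calls of 165. The genes given a change all had a mean of at least 5 TPM, so recovery of weaker genes was not measured. For the 15 panel genes an exact sign-flip permutation test over the 64 sign patterns of the 6 lines was added, adjusted over the panel.

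Of 41 gene lists fixed beforehand, 39 had at least 3 tested members. They were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over the 39 lists. A simulated shift of 0.5 in 1 list was called, and 0 of the other lists were. The simulated genes varied independently, while the estimated correlation in the data reached 0.687 for G2 and M phase genes. The simulation therefore cannot show how often camera calls lists of correlated genes falsely. camera called 17 lists with TGFβ against control, 19 with artesunate against TGFβ and 17 with artesunate against control, and fry called 25, 18 and 23. fry asks whether a list's genes move on balance one way and does not compare them with other genes. Of the 53 camera calls, 7 held with an estimated correlation.

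The genes named were set by a rule written before the data were examined, as were the comparisons, the gene lists and all alternatives except those said to be added. They are the panel of 15 genes, the 8 largest rises and falls among genes changed the same way in 6 lines with a mean of at least 5 TPM in the higher group, up to 4 members per list with the largest change (or the 2 most abundant where none changed), and the members of the receptor list. Genes that mark body position are outside this rule. Results of some genes the rule names are left out because they are withheld for evaluation.

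Whether the effects of TGFβ and of artesunate oppose each other was measured as Pearson's r across genes, with a simulation of no effect and with each effect taken from 3 different lines in 20 splits. Chance was judged by 32 swaps of treatment within lines and by 100 splits of the libraries, the real one included. Difference between the label series was tested as an interaction in limma. Alternatives were other pseudocounts (0.1 and 5), no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without mitochondrially encoded genes, no block, the 2 groups alone, no trend, array weights, an exact Wilcoxon signed-rank test, a 2-fold minimum, each label series alone and each line left out. limma-voom on the recovered reads, and averaging lines 2 and 5 and lines 4 and 6, were added after seeing the data. Of 37 HOX genes, which mark body position, lines 2 and 5 expressed the same 15, and lines 4 and 6 shared 10 of 11. Whether the lines of such a pair are independent of each other was not tested, so n = 6 may overstate the number of independent lines. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The raw reads were not analysed here.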

Results

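RNA from 6 primary fibroblast lines was sequenced after 3 treatments, which gave 18 libraries. Primary fibroblast lines are cells grown out of tissue, here labelled as heart, and are not established cell lines. Each line received the DMSO vehicle as control, TGFβ, or TGFβ with artesunate, so each of the 3 groups held 6 libraries. TGFβ is the cytokine that turns resting fibroblasts into contractile, matrix-secreting myofibroblasts, the cells that lay down scar in a fibrotic heart. Artesunate is an antimalarial drug whose endoperoxide bridge reacts with heme and iron. The study's title names MD2, the protein made from LY96 that holds lipopolysaccharide for the receptor TLR4, as a target against cardiac fibrosis. No group received artesunate without TGFβ, so the drug was measured only on top of TGFβ. Doses and treatment times are not given in the sources used here. Expression is in TPM, a read count divided by gene length and scaled to the same total in every library. A log2 change is a difference in log2(TPM + 1), which understates the change of weakly expressed genes. A lone value in parentheses after a gene list is the adjusted p of camera, a test of whether a list moved more than the other genes.

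The number of reads assigned to genes was recovered from the TPM values and is given with the SI prefix M for mega. Line 1 held 20.83 M reads in control, 17.12 M with TGFβ and 17.24 M with TGFβ and artesunate. In line 2 the same 3 libraries held 53.71, 38.04 and 36.22 M reads, and in line 3 they held 41.51, 38.06 and 50.69 M. In line 4 they held 35.51, 45.04 and 46.78 M reads, in line 5 23.05, 18.01 and 18.89 M, and in line 6 18.86, 19.18 and 21.06 M. The depths followed the 2 numbering series of the labels: lines 1, 5 and 6 had a median of 18.89 M reads and lines 2, 3 and 4 a median of 41.51 M. The 3 treatments had like depths, with medians of 29.28, 28.61 and 28.64 M reads. Mitochondrial transfer RNAs summed to between 6853.6 and 13332.3 TPM in lines 1, 5 and 6 and to between 403.7 and 1064.4 TPM in lines 2, 3 and 4. Each series holds all 3 treatments, so this split lies across the comparisons and not along them. Of the recovered counts from 11 to 100, 47.5% to 49.7% were even in lines 1, 5 and 6 and 58.6% to 61.3% in lines 2, 3 and 4. Whether the 2 reads of a fragment were counted once or separately is not given in the sources used here, so the depths of the series may not be in the same unit.

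Fibroblasts keep a record of their place in the body in the homeobox and T-box transcription factors they express. The genes of this paragraph were chosen after their levels had been seen. In line 1 GATA4, GATA6, TBX20, HAND2 and WT1, grouped here as heart-field factors, had a median of 42.9 TPM. In the other lines that median was at most 0.366 TPM. Single members were higher there: GATA6 had means from 4.39 to 14.8 TPM, and TBX20 of 3.54 and 2.99 TPM in lines 4 and 6. WT1 is also in the list of mesothelial and epicardial markers. GATA4, a driver of heart development, had a mean of 98.9 TPM in line 1 and at most 0.14 TPM in every other line. Lines 2, 3 and 5 expressed the lung and foregut mesenchyme factors TBX4, TBX5, FOXF1, FOXF2, HOXA5 and HOXB5, with medians of 147, 144 and 120 TPM, which were at most 1.87 TPM in lines 1, 4 and 6. TBX5 is also in the list of resting cardiac fibroblast genes. Its mean was 40.1, 41.9 and 40.7 TPM in lines 2, 3 and 5 and 3.69 TPM in line 1. Lines 4 and 6 expressed the body-wall and dermal factors EN1, TBX15, ZIC1 and EMX2, with medians of 76.7 and 65.4 TPM, which were at most 0.442 TPM in the other 4 lines. The 3 libraries of every line stood in the same set, 0 of 18 being out of place.

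**Figure D1:**
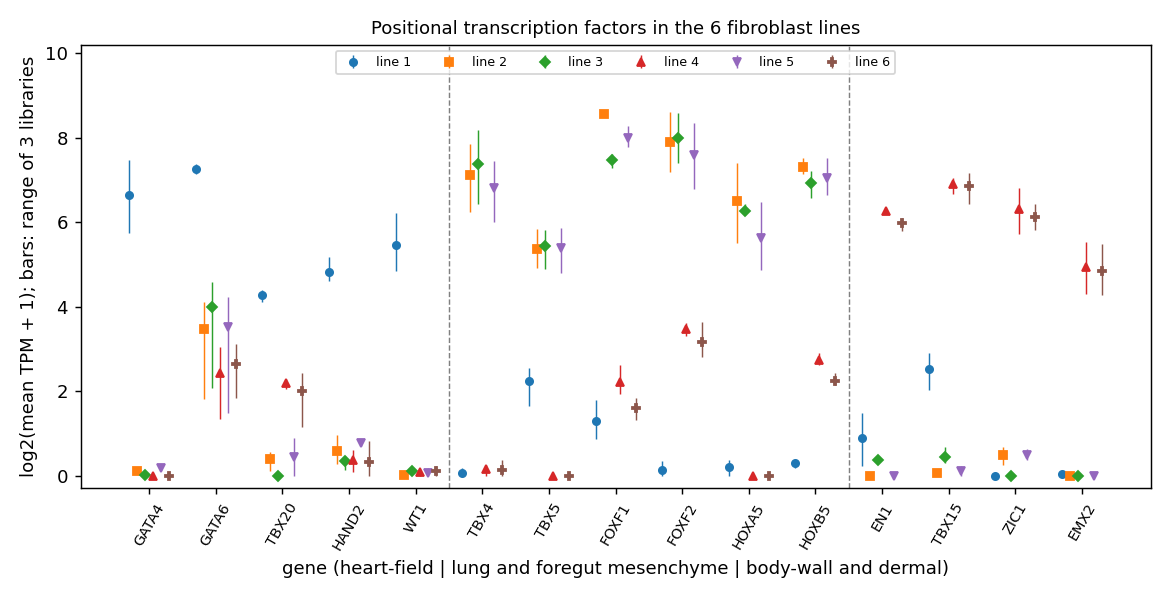
Level, as log2(TPM + 1), of position-marking transcription factors in each of the 6 lines: the mean of 3 libraries, with bars for their range. Line 1 stands apart from lines 2, 3 and 5 and from lines 4 and 6; GATA4 is at 98.9 TPM in line 1 and at most 0.14 TPM elsewhere.

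The first comparison, TGFβ against control, asks what the cytokine does to these cells. TGFβ switched on the myofibroblast programme: scar matrix, contractile fibres, the pathway's own feedback genes and the amino acid and secretory machinery that collagen production needs all rose. Genes of lysosomes, of cholesterol synthesis and of fat cells fell, the lysosome call being lost without line 1 (adjusted p = 0.0804). These are calls of camera with a preset correlation: matrix glycoproteins, proteases, contractile and feedback genes kept theirs with an estimated one, and the others did not (adjusted p = 0.215 with an estimated correlation for fibrillar collagens, 0.158 for ATF4, 0.0935 for the unfolded protein response, 0.323 for lysosomes, 0.294 for cholesterol synthesis and 0.288 for fat cells). Of 17462 genes tested, 3538 changed at an adjusted p under 0.05 in limma, 1326 up and 2212 down, and 702 of them by at least 2-fold, 319 up and 383 down. The lower share of rises, 37.5%, depends on scaling: it was 49.5% with median-of-ratios scaling, 50.7% with quantile normalization and 50.3% with limma-voom on the recovered reads. The count fell to 1863 without line 4 and to 2150 without line 6. The largest rises belonged to COMP and ELN, which encode a cartilage matrix protein and elastin, and to MDFI, COL10A1, TSPAN2, POSTN, INHBE and CTGF. COMP is listed close to 0 in control, at 0.0984 ± 0.0724 TPM (SD, n = 6), and reached 114 ± 201 TPM with TGFβ. The largest falls included NPTX1, ADAMTS15, SECTM1, PRELP, SLC7A14, TNXB and IGSF10, among them the matrix proteins PRELP and tenascin X.

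The scar matrix rose broadly. COL1A1, the main chain of collagen I on chromosome 17 (GRCh38/hg38, 50183289 to 50201632), rose by 1.93 ± 0.28 (SE, n = 6 lines, adjusted p = 0.00063), from a mean of 4870 ± 4060 TPM (SD) in control to 14200 ± 7870 TPM with TGFβ. Among the 10 fibrillar and fibril-associated collagens 7 rose and 1 fell, and the same numbers passed when adjusted over the list alone. COL11A1 and COL5A1 led the rises, COL1A2 rose by 0.89 ± 0.14, COL14A1 fell, and COL3A1 did not pass (0.00 ± 0.38, adjusted p = 1). The mean of COL3A1 hides lines that went opposite ways. It changed by 2.1 in line 3, by -1.36 in line 4 and by -1.27 in line 6, and by -0.12 to 0.44 in the others. The list rose in camera (adjusted p = 3.8e-05; adjusted p = 0.215 with an estimated correlation). Matrix glycoproteins, the adhesive and elastic proteins between the fibres, had 21 members up and 3 down of 31, the same when adjusted over the list alone, and kept their call with an estimated correlation (adjusted p = 7.34e-14 and 0.0384). POSTN, a matricellular protein of activated fibroblasts on chromosome 13 (37562583 to 37598844), rose by 3.64 ± 0.54 (adjusted p = 0.00076), and FN1 and CTGF rose with it. Proteases and their inhibitors had 10 of 23 members up, 14 when adjusted over the list alone, SERPINE2 and ADAM12 among them (adjusted p = 2.13e-07, and 0.0384 with the estimate). Enzymes that fold and crosslink collagen had 10 up and 1 down of 23, alike when adjusted over the list alone, with PLOD2 and LOX among them (adjusted p = 5.28e-06; adjusted p = 0.151 with an estimated correlation). Basement membrane and network collagens had 7 up, COL10A1 and COL8A1 among them, and 3 down of 15, or 7 and 6 over the list alone, and the list did not pass in camera (adjusted p = 0.0818) but did in fry (adjusted p = 0.0384, up).

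The contractile apparatus followed. Of 20 myofibroblast contractile genes 12 rose, 14 when adjusted over the list alone, and none fell (camera adjusted p = 1.17e-11, and 0.0384 with the estimate). ACTA2, smooth muscle actin on chromosome 10 (88935074 to 88991339), rose by 2.44 ± 0.43 in 6 of 6 lines (adjusted p = 0.0019). Calponin CNN1 on chromosome 19 (11538717 to 11550323) rose by 2.11 ± 0.29 and transgelin TAGLN by 2.10 ± 0.21, with TPM1 and the collagen receptor ITGA11 beside them. ACTA2 shares reads with near-identical actin genes such as ACTG2, so its level is uncertain to that extent. Targets of YAP and SRF, the factors that read cell tension, had 7 up and 1 down of 18, the same over the list alone, with CTGF and CYR61 in front (adjusted p = 4.58e-05; adjusted p = 0.165 with an estimated correlation). TGFβ pathway targets and feedback genes had 17 up and 2 down of 29, or 19 and 2 adjusted over the list alone, among them PMEPA1, LTBP2 and the fibrosis-driving cytokine IL11 (adjusted p = 3.76e-10, and 0.0384 with the estimate). Growth factors and their receptors had 12 up and 5 down of 32, or 14 and 6 over the list alone, with FZD8 and WNT5A up and BMP4 down (adjusted p = 0.00117; adjusted p = 0.106 with an estimated correlation). The exact sign-flip test of the 15 panel genes gave its smallest possible p of 0.0312, adjusted to 0.0425, for the 12 genes of the panel that moved the same way in 6 of 6 lines.

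Genes that feed and fold secreted protein rose as well. The ATF4 response, which brings in amino acids and makes serine and proline, had 23 of 30 members up, 25 when adjusted over the list alone, and none down, including the transporter SLC7A5 and the enzymes ASNS and PSAT1 (adjusted p = 7.58e-17; adjusted p = 0.158 with an estimated correlation). Proline, serine and glycine synthesis, which supplies the residues collagen is richest in, had 11 up and 1 down of 16, or 12 and 1 over the list alone, MTHFD2 and PYCR1 among them (adjusted p = 1.36e-09; adjusted p = 0.0686 with an estimated correlation). The unfolded protein response of the endoplasmic reticulum had 19 of 24 up, 22 over the list alone, with HYOU1 and XBP1 (adjusted p = 1.95e-14; adjusted p = 0.0935 with an estimated correlation). Cell cycle genes rose. Of 26 G2 and M phase genes 15 passed, 25 over the list alone, CCNA2 among them (adjusted p = 1.11e-11, and 0.254 with an estimated correlation). Of 25 S phase genes 6 passed, 9 over the list alone, CDC45 among them (adjusted p = 3.12e-06, and 0.332 with an estimated correlation). The S phase median was 1.097 in line 4, 0.497 in line 6 and 0.286 in line 5, but only 0.015 to 0.073 in lines 1, 2 and 3. Cholesterol synthesis fell, with 9 of 24 members down, 12 over the list alone, LSS and HSD17B7 in front (adjusted p = 0.000632; adjusted p = 0.294 with an estimated correlation). Lysosome and autophagy genes had 8 down and 1 up of 27, or 10 and 2 over the list alone, with the lysosomal GPNMB and CTSL down (adjusted p = 0.0149; adjusted p = 0.323 with an estimated correlation), a call that was lost without line 1 (adjusted p = 0.0804).

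Camera called none of the following lists. fry, which asks only whether a list moves on balance one way, called resting fibroblast genes (adjusted p = 0.000416), NRF2 targets (0.00533), iron handling (0.0195) and interferon-stimulated genes (0.0386), each down. NRF2 targets, the antioxidant genes, had 10 down and 3 up of 25, NQO1 and AKR1C2 down, alike over the list alone (list adjusted p = 0.0833); AKR1C2 shares sequence with AKR1C1 and AKR1C3. HMOX1, heme oxygenase on chromosome 22 (35380361 to 35394214), did not change (-0.33 ± 0.16, adjusted p = 0.17), but passed without line 4 (adjusted p = 0.0383). Genes of resting cardiac fibroblasts had 10 down and 2 up of 20, or 10 and 3 over the list alone, with CFD down and PI16 up (adjusted p = 0.0979), and a list median below 0 in 6 of 6 lines. Interferon-stimulated genes had 5 down and 1 up of 21, IFIT1 and IFIT3 down (0.127), iron handling 7 down and 2 up of 26, SLC40A1 down (0.496), and fatty acid synthesis 4 down and 1 up of 14, LPIN1 down (0.708). p53 targets had 3 up and 4 down of 23, CDKN2B up (0.848), hypoxia and glycolysis 1 up and 5 down of 29 (0.376), and nuclear-encoded oxidative phosphorylation 2 up and 7 down of 32, SDHA down (0.497). Immediate early genes had 4 up and 1 down of 20, EGR2 up and ZFP36 down (0.285), and prostaglandin, retinoid and steroid responsive genes 2 up and 3 down of 17, PTGES down (0.56). When adjusted over the list alone, iron handling had 10 down and 4 up, oxidative phosphorylation 8 down, fatty acid synthesis and p53 targets 5 down each, prostaglandin responsive genes 4 down and immediate early genes 2 down, and the other counts were alike.

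The receptor axis named in the title was present at low to moderate levels. LY96, on chromosome 8 (73991352 to 74029087), had a mean of 59.1 ± 63.1 TPM in control and 40.1 ± 26.3 TPM with TGFβ and did not change (-0.34 ± 0.21, adjusted p = 0.28). In control it stood at 185.8 TPM in line 1 and at 18.3 to 46.52 TPM in the other lines. With TGFβ it changed by -1.14 in line 1 and by -0.68 to 0.31 in the others. TLR4, on chromosome 9 (117704175 to 117724730), did not change (0.03 ± 0.18, adjusted p = 0.94). TLR4 stood at 29.05 TPM in control of line 1 and at no more than 1.817 TPM in control of the other 5 lines, so its mean over lines describes none of them. Of the 14 tested genes of the TLR4 and MD2 complex and its adaptors 2 fell, the adaptor MYD88 and the kinase-like inhibitor IRAK3, and none rose, or 3 down and 1 up over the list alone (list adjusted p = 0.46 in camera; 0.00907, down, in fry). MYD88 did not pass without line 4 (adjusted p = 0.0563). NF-κB targets, the genes such a receptor would drive, had 3 up and 3 down of 27, or 3 and 4 over the list alone, TNFAIP6 and LIF up and SOD2 down. Their median was -0.11, their mean 0.03 and the test pointed up (adjusted p = 0.848).

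Signs of RNA quality and of other cell types were measured beside these programmes. Among lists that camera did not call, fry called nuclear-retained RNAs (adjusted p = 0.00203) and Schwann markers (0.00278) down and smooth muscle markers (0.00888) up. Mitochondrially encoded mRNAs had none changed of 13, with a median of -0.05 while the test pointed up (adjusted p = 0.848), as for MT-CO1 and MT-CO3. Ribosomal proteins had 1 of 32 down and none over the list alone (adjusted p = 0.0818), and nuclear-retained RNAs 2 of 7 down (0.395). Replication-dependent histones, which poly(A) selection mostly removes and whose copies share reads, had 4 of 10 down, HIST1H2BK among them (adjusted p = 0.0473; adjusted p = 0.288 with an estimated correlation), a call lost without line 1 (adjusted p = 0.146), with a pseudocount of 5 (0.0556), without the trend (0.0525), with array weights (0.0501) and with limma-voom (0.062). Fat cell markers had 3 of 4 down, PPARG and PLIN4 among them (adjusted p = 0.0143; adjusted p = 0.288 with an estimated correlation). Endothelial markers had 1 of 5 up (0.0891), smooth muscle and pericyte markers 1 of 9 up, MCAM (0.0891), Schwann markers 1 of 3 down, MBP, or 3 over the list alone (0.0864), and mesothelial markers 1 of 5 down, KRT19 (0.833). Cardiomyocyte markers had none of 3 changed, with a median of -0.06 and a mean of 0.35 (0.708), and macrophage markers none of 3, with a median of 0.36 and a mean of -0.03 (0.595). Lymphocyte and mast cell markers, with 1 tested gene, and erythroid and platelet markers, with 0, could not be tested as lists.

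The next comparison, TGFβ with artesunate against TGFβ, asks what the drug does to activated fibroblasts. Artesunate took down the contractile genes, the fibrillar collagens, cholesterol synthesis and the cell cycle, and it raised antioxidant, ferritin and p53 target genes. Of these lists the antioxidant NRF2 targets alone kept their call with an estimated correlation: the others had adjusted p = 0.0847 with an estimated correlation for contractile genes, 0.18 for fibrillar collagens, 0.0673 for cholesterol synthesis, 0.0847 for G2 and M phase, 0.28 for S phase, 0.28 for iron handling and 0.226 for p53 targets. The pathway's targets and feedback genes did not fall as a list, and POSTN did not pass, moving up in some lines and down in others. Of 17462 genes 2675 changed, 1740 up and 935 down, and 280 by at least 2-fold, 52 up and 228 down. The share of rises, 65%, was 44.1% with median-of-ratios scaling, 52.5% with quantile normalization, 50% when mitochondrially encoded genes were left out of the scaling and 42.5% with limma-voom. The count fell to 1113 without line 3, 1466 without line 4 and 1644 without line 5. GDF15, a stress-induced cytokine on chromosome 19 (18374731 to 18389176), rose most, by 2.08 ± 0.27 (SE, n = 6 lines, adjusted p = 7e-04), from 262 ± 124 TPM to 1260 ± 831 TPM (SD). TFPI2, SRXN1, ABCC3 and PANX2 were other large rises. LMOD1, which seeds actin filaments in muscle, fell most, by 2.44 on the log2 scale, and ACTG2, MRVI1, FABP3 and the proliferation genes MKI67, KIF20A, CDC20 and MYBL2 were next.

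Contraction and collagen fell together. Of 20 contractile genes 9 fell, 10 when adjusted over the list alone, and none rose (adjusted p = 6.81e-08; adjusted p = 0.0847 with an estimated correlation). ACTA2 fell by 1.64 on the log2 scale (SE 0.43, adjusted p = 0.022) from 509 ± 452 TPM to 189 ± 160 TPM, in 6 of 6 lines, but missed the threshold without line 3, 4 or 6 (adjusted p = 0.0623, 0.0844 and 0.0718). CNN1 fell by 1.72 and TAGLN by 1.04, and both still passed with each line left out in turn. The fibrillar collagens had 5 of 10 down, 9 over the list alone, and none up (adjusted p = 7.09e-07; adjusted p = 0.18 with an estimated correlation). COL1A1 fell by 1.06 (SE 0.28, adjusted p = 0.021), most in line 3, and missed the threshold without line 4 or 5 (adjusted p = 0.0563 and 0.0533) and with quantile normalization (adjusted p = 0.121). COL1A2 and COL14A1 fell too, and COL3A1 fell by 1.36 but missed the threshold without line 1, 3, 4 or 5 (adjusted p = 0.0593, 0.0762, 0.0526 and 0.0609). Matrix glycoproteins had 10 of 31 down, 12 over the list alone (adjusted p = 2.45e-08, and 0.082 with an estimated correlation). POSTN (0.05 ± 0.54), FN1 (-0.23 ± 0.26) and COMP (-0.47 ± 0.53) did not pass in limma. POSTN changed by 0.39, 0.77 and 1.33 in lines 2, 3 and 5 and by -0.98, -0.6 and -0.63 in lines 1, 4 and 6. COMP changed by 0.65 and 0.36 in lines 2 and 5 and by -1.29 to -0.5 in the others. CTGF moved down in 6 of 6 lines by -0.89 ± 0.61, which did not pass in limma (adjusted p = 0.36) and did in a fit of the 2 groups alone (adjusted p = 0.00722). Collagen folding enzymes had 3 of 23 down, 2 over the list alone (adjusted p = 0.00383; adjusted p = 0.318 with an estimated correlation), and YAP and SRF targets 2 of 18 down, VCL among them (adjusted p = 0.0262; adjusted p = 0.358 with an estimated correlation), a call lost without line 3 (adjusted p = 0.0789).

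Other parts of the TGFβ response did not fall as lists. TGFβ pathway targets and feedback genes had 4 of 29 up and none down, alike over the list alone, the repressor TGIF1 among them (list adjusted p = 0.594). IL11 moved up in 6 of 6 lines by 1.02 ± 0.42 and did not pass in limma with all 3 groups (adjusted p = 0.12). It passed in the fit of the 2 groups alone (adjusted p = 0.00245), in the exact sign-flip test (adjusted p = 0.0468) and with limma-voom (adjusted p = 0.0304). The sign-flip test gave the same exact p of 0.0312, adjusted to 0.0468, for each panel gene that moved the same way in 6 of 6 lines, among them COL1A1, COL1A2, COL3A1, ACTA2, TAGLN, CNN1, CTGF and HMOX1. Proteases had 5 of 23 up and 1 down, MMP11, alike over the list alone (0.595), and basement membrane collagens none of 15 changed (0.0566). ATF4 targets had 3 of 30 up, GDF15 and SLC7A11 among them, and 2 over the list alone (0.109). Proline and serine synthesis had 1 of 16 down, SHMT1, with a median of 0.10 against a mean of -0.004 and a test pointing down (0.617). The unfolded protein response had 2 up and 5 down of 24, or 2 and 6 over the list alone, with the chaperones CALR and PDIA4 down (0.108). Growth factors had 5 up and 6 down of 32, with FGF2 up and BMP4 down (0.195).

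With artesunate added to TGFβ, antioxidant and iron handling genes rose and cell cycle genes fell. Without an arm of artesunate alone, effects of the drug itself cannot be told from changes in the TGFβ response. NRF2 targets had 19 of 25 up, 21 over the list alone, and none down, and kept their call with an estimated correlation (adjusted p = 4.54e-14 and 0.0299). HMOX1, which opens the heme ring and frees its iron, rose by 1.13 ± 0.16 (adjusted p = 0.001) from 330 ± 293 TPM to 681 ± 562 TPM, and NQO1, SRXN1 and OSGIN1 rose too. Iron handling had 7 up and 2 down of 26, or 9 and 2 over the list alone, with the ferritin genes FTH1 and FTL and the transferrin receptor TFRC up (adjusted p = 0.0349; adjusted p = 0.28 with an estimated correlation). That call was lost without line 1 (adjusted p = 0.0504), with median-of-ratios scaling (0.0551), with quantile normalization (0.155) and among genes with a mean of at least 5 TPM (0.137), and FTH1 and FTL share reads with many pseudogenes. All 26 G2 and M phase genes fell (adjusted p = 1.54e-30; adjusted p = 0.0847 with an estimated correlation), with a list median of -1.39. MKI67, a proliferation marker on chromosome 10 (128096659 to 128126385), fell by 2.21 (SE 0.22, adjusted p = 0.00023) from 17.9 ± 8.35 TPM to 3.61 ± 3.26 TPM. S phase genes had 12 down and 1 up of 25, or 19 and 1 over the list alone, RRM2 and CDC45 down (adjusted p = 8.12e-10; adjusted p = 0.28 with an estimated correlation). p53 targets and cell cycle inhibitors had 10 of 23 up, or 13 up and 2 down over the list alone, with CDKN1A, TNFRSF10B and FDXR (adjusted p = 0.000448; adjusted p = 0.226 with an estimated correlation).

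Lipid and resting-state genes fell. Cholesterol synthesis had 15 of 24 down, 18 over the list alone, HMGCS1 among them (adjusted p = 8.47e-15; adjusted p = 0.0673 with an estimated correlation), on top of the fall with TGFβ. Fatty acid synthesis had 3 down and 2 up of 14, or 4 and 2 over the list alone, with FADS2 down and ME1 up (adjusted p = 0.0106; adjusted p = 0.318 with an estimated correlation). Genes of resting cardiac fibroblasts, which would rise if the cells returned to rest, had 6 of 20 down, 8 over the list alone, and none up, including DCN and ABCA8, and kept their call with an estimated correlation (adjusted p = 1.3e-06 and 0.009). Prostaglandin, retinoid and steroid responsive genes had 3 of 17 down, CRABP2 among them (adjusted p = 0.0349; adjusted p = 0.28 with an estimated correlation), a call lost without line 3 (adjusted p = 0.0622) and under 3 scalings (adjusted p from 0.0676 to 0.0865). Interferon-stimulated genes had 3 of 21 down, GBP1 among them (adjusted p = 0.00383; adjusted p = 0.339 with an estimated correlation). Lysosome and autophagy genes had 7 up and 3 down of 27, or 9 and 3 over the list alone, with SQSTM1 up and LIPA down (0.126 in camera; 0.0423, up, in fry), and hypoxia and glycolysis 2 of 29 up, HK1 among them (0.141). Immediate early genes had 2 up and 1 down of 20, or 2 and 2 over the list alone, with a median of 0.08 and a test pointing down (0.893).

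LY96 (-0.11 ± 0.21, adjusted p = 0.79) and TLR4 (0.02 ± 0.18, adjusted p = 0.96) did not change with artesunate. Of the 14 genes of the receptor complex 3 rose, the kinase IRAK1 most clearly (0.51 ± 0.08, adjusted p = 0.0015), and none fell, alike over the list alone (list adjusted p = 0.596). NF-κB targets had 3 up and 1 down of 27, or 4 and 1 over the list alone (0.617).

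Mitochondrial RNA changed shape with artesunate. Mitochondrially encoded mRNAs had 7 of 13 down and 1 up (adjusted p = 0.000377; adjusted p = 0.337 with an estimated correlation). MT-CO1 (chromosome M, 5904 to 7445) fell by 1.17 on the log2 scale (SE 0.15) from 27900 ± 3570 TPM to 12500 ± 2520 TPM, while MT-ND2 (chromosome M, 4470 to 5511) rose by 1.16 ± 0.12 from 3790 ± 405 TPM to 8510 ± 1230 TPM, each in 6 of 6 lines. MT-ND6 lies on the other strand and is uncertain because the counting's use of strand is not given in the sources used here. The mitochondrial share of TPM had a median of 13.92% with TGFβ and 10.23% with artesunate. Nuclear-encoded oxidative phosphorylation had 8 of 32 up, 9 over the list alone, CYC1 among them (adjusted p = 0.00455; adjusted p = 0.377 with an estimated correlation), a call lost with median-of-ratios scaling (0.0503), quantile normalization (0.23) and limma-voom (0.0523). Ribosomal proteins had 8 of 32 up, 21 over the list alone (adjusted p = 6.17e-07; adjusted p = 0.355 with an estimated correlation), and their pseudogenes share reads with them. Smooth muscle and pericyte markers had 2 of 9 down, or 3 down and 1 up over the list alone (adjusted p = 0.0303; adjusted p = 0.154 with an estimated correlation), a call lost without line 1 (adjusted p = 0.0504) and among genes with a mean of at least 5 TPM (0.0626). Histones had 1 of 10 down (0.0648), mesothelial markers 1 of 5 (0.617), and nuclear-retained RNAs none of 7, with a median of 0.06 and a mean of -0.09 (0.617). Endothelial (0.383), cardiomyocyte (0.101; fry 0.00767, down), macrophage (0.683) and Schwann (0.097; fry 0.0475, down) markers had no member changed over all genes, and over the list alone 1 endothelial and 1 cardiomyocyte marker fell. Fat cell markers had none changed, with a median of 0.04 and a test pointing down (0.966).

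**Figure D2:**
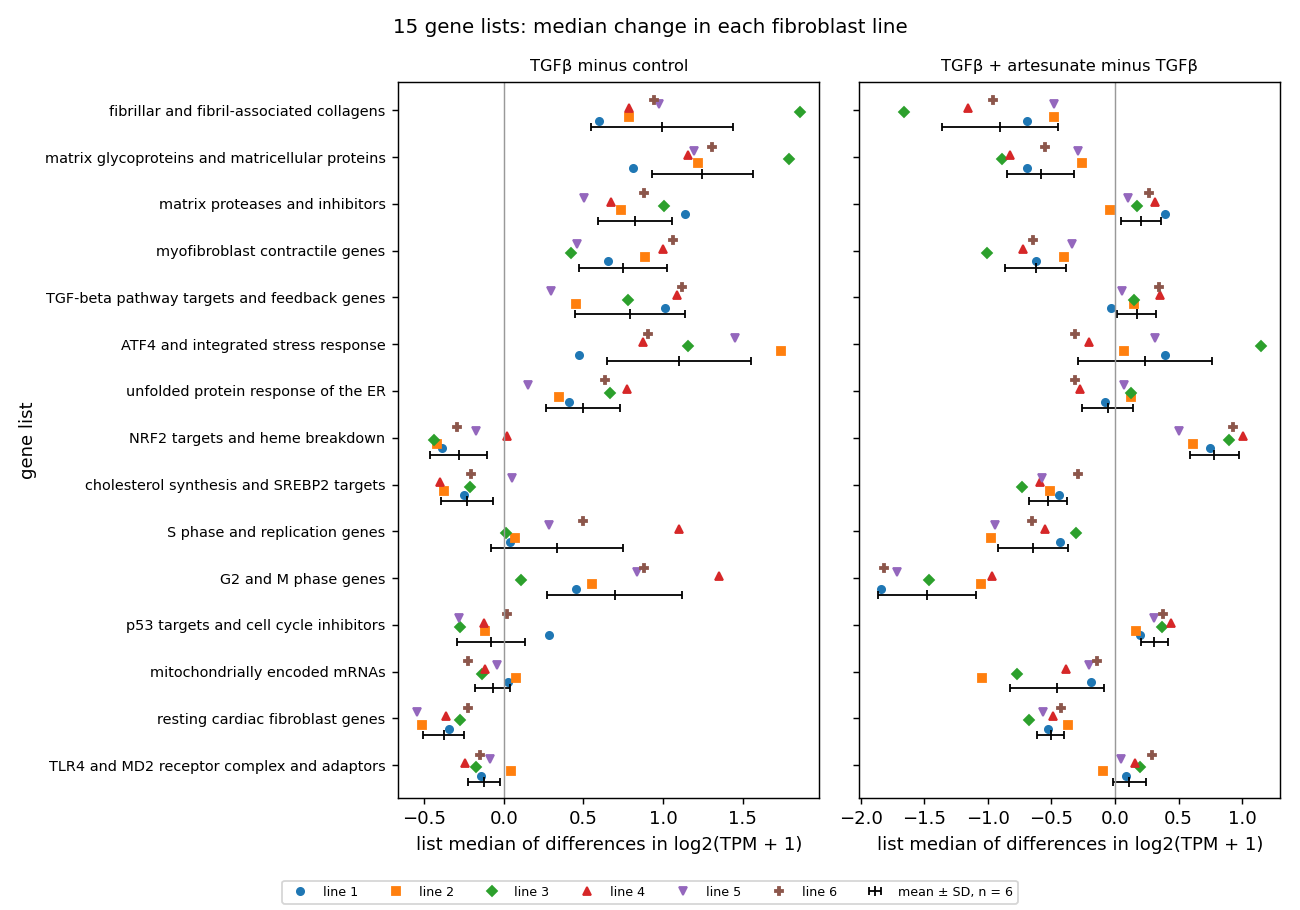
Median change in log2(TPM + 1) of 15 gene lists in each of the 6 lines, with TGFβ against control on the left and TGFβ with artesunate against TGFβ on the right; bars give the mean and SD over lines. Contractile genes lie above 0 in 6 lines on the left and below 0 in 6 lines on the right, and G2 and M phase genes fall to -0.97 or lower in each line on the right.

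Whether artesunate reversed the TGFβ response was measured across genes, which are not independent replicates. Both effects use the same TGFβ libraries, so chance alone gives a negative correlation, of -0.501 on average in data simulated with no effect. The observed Pearson correlation across genes was -0.043, and the covariance was -0.008 against -0.024 in the simulation. With each effect measured on 3 different lines the correlation was 0.046 on average over 20 splits, from -0.062 to 0.115. Of the 1326 genes raised by TGFβ, 168 were lowered by artesunate (71 expected of independent lists), 167 were raised further (132 expected) and 991 did not change. Of the 2212 genes lowered by TGFβ, 252 were raised (220 expected), 205 were lowered further (118 expected) and 1755 did not change. The median artesunate effect was 0.02 on the raised genes and 0.02 on the lowered ones. In the separate lines the raised genes lost a median of -0.017% of their rise, with a range from -17.9% to 9.15%. For the lowered genes the median artesunate effect in the separate lines was -0.09, opposite in sign to that over all lines, and was above 0 in 3 of 20 splits. By the same kind of ratio they regained a median of -15.8% of their fall over the splits, with a range from -52.5% to 6.41%.

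The last comparison, TGFβ with artesunate against control, shows where the treated cells ended. They kept the pathway's targets, the ATF4 response and matrix glycoproteins above control, while G2 and M phase, cholesterol synthesis and resting fibroblast genes ended below it. Of these lists the resting fibroblast genes alone kept their call with an estimated correlation: the others had adjusted p = 0.163 with an estimated correlation for the pathway's targets, 0.255 for ATF4, 0.429 for matrix glycoproteins, 0.441 for G2 and M phase and 0.163 for cholesterol synthesis. In limma 6252 of 17462 genes differed, 3045 higher and 3207 lower, and 1381 by at least 2-fold, 456 higher and 925 lower. Large rises included COMP, SERPINE2, AMIGO2, IL11, POSTN, PMEPA1 and FOXS1, and the largest falls were ADAMTS15, PRELP, FABP3, OLFML1, AQP3, SEPP1, FGL2 and BMP4.

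ACTA2 (0.81 ± 0.43, adjusted p = 0.16) and COL1A2 (0.11 ± 0.14, adjusted p = 0.57) did not differ from control, nor did CNN1 (0.39 ± 0.29, adjusted p = 0.31), which passed without line 3 (adjusted p = 0.048). TAGLN stayed 1.06 ± 0.21 higher, FN1 1.36 ± 0.26 and CTGF 2.57 ± 0.61. COL1A1 stayed 0.86 ± 0.28 higher (adjusted p = 0.026), but not without line 2 or 5 (adjusted p = 0.0991 and 0.0866), and COL3A1 fell by 1.36 below control, but not without line 4 (adjusted p = 0.0573). Contractile genes had 7 higher and 4 lower of 20, or 8 and 4 over the list alone, TPM1 higher and LMOD1 lower (0.114; fry 0.021, up), and fibrillar collagens 3 and 3 of 10, alike over the list alone, with a median of 0.18 and a mean of -0.09 (0.647). TGFβ targets and feedback genes had 18 higher and 4 lower of 29, alike over the list alone (adjusted p = 8.66e-06; adjusted p = 0.163 with an estimated correlation), PMEPA1 among the higher. Proteases had 14 higher and 1 lower of 23, or 15 and 3 over the list alone, MMP1 and MMP3 higher (adjusted p = 0.00017; adjusted p = 0.163 with an estimated correlation), and matrix glycoproteins 18 higher and 6 lower of 31, or 19 and 6 over the list alone, BGN higher (adjusted p = 0.00966; adjusted p = 0.429 with an estimated correlation; 0.0662 among genes with a mean of at least 5 TPM). Collagen folding enzymes (8 higher and 2 lower of 23, 0.132), basement membrane collagens (6 and 5 of 15, 0.746), YAP and SRF targets (5 and 1 of 18, 0.114) and growth factors (12 and 9 of 32, 0.257) did not pass as lists in camera, and fry called growth factors up (0.00381). Adjusted over the list alone, 1 more basement membrane collagen was higher and 1 more growth factor gene lower.

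The ATF4 response stood highest, with 27 of 30 members above control, 28 over the list alone, TRIB3 among them (adjusted p = 3.94e-13; adjusted p = 0.255 with an estimated correlation). The unfolded protein response had 14 higher and 1 lower of 24, or 14 and 2 over the list alone, ERN1 higher (adjusted p = 2.29e-05; adjusted p = 0.429 with an estimated correlation), and proline and serine synthesis 12 higher and 1 lower of 16, or 14 and 1 over the list alone, PSAT1 higher (adjusted p = 2.29e-05; adjusted p = 0.219 with an estimated correlation). NRF2 targets had 15 higher and 2 lower of 25, SLC7A11 higher and AKR1C2 lower, alike over the list alone (adjusted p = 2.29e-05; adjusted p = 0.219 with an estimated correlation), and HMOX1 was 0.80 ± 0.16 higher. p53 targets had 10 higher and 2 lower of 23, or 11 and 3 over the list alone, CDKN1A higher (adjusted p = 0.0283; adjusted p = 0.441 with an estimated correlation), a call lost without line 1 (adjusted p = 0.0679), with quantile normalization (0.204) and among genes with a mean of at least 5 TPM (0.132). Cholesterol synthesis had 22 of 24 lower, alike over the list alone, LSS among them (adjusted p = 2.45e-12; adjusted p = 0.163 with an estimated correlation). G2 and M phase genes had 20 of 26 lower, 22 over the list alone, KIF20A and MKI67 among them (adjusted p = 5.54e-07; adjusted p = 0.441 with an estimated correlation); line 4 alone had a list median above 0. Resting fibroblast genes had 12 lower and 2 higher of 20, or 13 and 2 over the list alone, CFD and ABCA8 lower (adjusted p = 0.00017, and 0.0437 with an estimated correlation). Interferon-stimulated genes had 11 lower and 1 higher of 21, alike over the list alone, IFIT1 and OAS3 lower (adjusted p = 0.0021; adjusted p = 0.44 with an estimated correlation).

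The receptor axis again gave no change of LY96 (-0.45 ± 0.21, adjusted p = 0.12) or TLR4 (0.04 ± 0.18, adjusted p = 0.88). Of its 14 genes 3 were higher, IRAK1 among them, and 3 lower, IRAK3 and TLR3 among them, or 3 and 4 over the list alone (list adjusted p = 0.805), and NF-κB targets had 6 higher and 6 lower of 27, or 6 and 7 over the list alone (0.76). Mitochondrially encoded mRNAs had 7 of 13 lower and 1 higher (adjusted p = 0.0268; adjusted p = 0.561 with an estimated correlation), a call lost without line 3 (adjusted p = 0.0797). Histones had 7 of 10 lower, HIST1H4H among them (adjusted p = 0.00376; adjusted p = 0.219 with an estimated correlation). Ribosomal proteins had 3 of 32 higher and none over the list alone (adjusted p = 0.0268; adjusted p = 0.747 with an estimated correlation), a call lost without line 3 (adjusted p = 0.104), without line 5 (adjusted p = 0.175), among genes with a mean of at least 5 TPM (0.12) and under each other scaling. Schwann markers had 3 of 3 lower, MBP among them (adjusted p = 0.0268; adjusted p = 0.255 with an estimated correlation; 0.0765 with no filter). Fat cell markers had 3 of 4 lower, FABP4 among them, and 4 over the list alone (adjusted p = 0.0346; adjusted p = 0.441 with an estimated correlation), a call lost without line 4 (adjusted p = 0.0667) or line 6 (adjusted p = 0.0643) and with mitochondrially encoded genes left out of the scaling (0.0509). Camera did not call the other lists. fry called fatty acid synthesis (0.00359), prostaglandin responsive genes (0.00274), nuclear-retained RNAs (0.00136) and cardiomyocyte markers (0.0129) down and iron handling (0.0189) up. Fatty acid synthesis had 3 higher and 6 lower of 14, or 3 and 9 over the list alone (0.0646), iron handling 9 and 5 of 26, or 10 and 5 over the list alone (0.24), and S phase genes 1 and 5 of 25 (0.277). Hypoxia genes had 4 higher and 6 lower of 29 (0.766), oxidative phosphorylation 9 and 4 of 32 (0.24), lysosome genes 6 and 9 of 27, or 7 and 9 over the list alone (0.746), and immediate early genes 5 and 6 of 20, or 7 and 6 over the list alone (0.396). Prostaglandin responsive genes had 3 higher and 9 lower of 17 (0.071) and nuclear-retained RNAs 3 of 7 lower (0.365). Endothelial markers had 1 of 5 higher and none over the list alone (0.571), smooth muscle markers 2 higher and 3 lower of 9 (0.805), cardiomyocyte markers 1 of 3 lower (0.433) and macrophage markers 1 of 3 higher, with 1 lower as well over the list alone (0.571). Mesothelial markers had 1 of 5 lower, with a median of 0.28, a mean of -0.34 and a test pointing down (0.805).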

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

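The values below were picked because 1 of the 6 lines stood far from the others, its gap to the nearest line divided by the whole range being above the 95% limit of Dixon's test. The gene levels and gene differences compared are those of genes named in the report. Of 340 groups of 6 values compared, 29 passed, which is 8.53%, where chance passes about 1 in 20. They were 18 of 193 gene differences, 8 of 117 list medians and 3 of 30 gene levels. Line 3 held 13 of them, line 1 held 11, line 2 held 3, line 6 held 2, and lines 4 and 5 held 0. No explanation was tested for them.

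Line 3 had the strongest collagen response in both directions. With TGFβ the fibrillar collagens had a median change of 1.86 in line 3 and 0.60 to 0.98 in the other lines (ratio 0.702), COL1A1 changed by 3.62 against 1.18 to 2.06 (0.642), COL5A1 by 2.84 against 1.55 to 1.95 (0.689), and the Wnt receptor FZD8 by 4.49 against 2.20 to 2.97 (0.665). With artesunate added, COL1A1 changed by -2.59 in line 3 against -0.92 to -0.54 in the others (0.813), COL1A2 by -1.46 against -0.77 to -0.42 (0.667), COL3A1 by -3.08 against -1.39 to -0.74 (0.725) and CTGF by -1.72 against -0.84 to -0.44 (0.687). Line 3 also had the largest artesunate rise of GDF15, 3.60 against 1.13 to 1.96 (0.666), of IRAK1, 0.86 against 0.33 to 0.51 (0.661), of the respiratory gene CYC1, 0.81 against 0.31 to 0.44 (0.736), and of the fat cell markers, 0.82 against -0.12 to 0.19 (0.676). CNN1 ended below control in line 3 alone, at -1.16 against 0.48 to 1.30 (0.666).

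Line 1 started from another level. ACTA2 in control was 9.40 in log2(TPM + 1) in line 1 and 5.12 to 5.74 in the others (0.854). TLR4 was 4.91 against 0.13 to 1.49 in control (0.715) and 5.38 against 0.06 to 1.63 with TGFβ (0.704). With TGFβ line 1 had smaller changes of COL10A1, 0.67 against 3.73 to 5.50 (0.633), and of CYR61, 0.11 against 1.72 to 2.36 (0.716), and a lower median of hypoxia and glycolysis genes, -0.86 against -0.13 to 0.04 (0.817). With artesunate added, line 1 had the largest difference of HMOX1, 1.55 against 0.95 to 1.16 (0.648), and the smallest of SHMT1, -0.07 against -0.80 to -0.54 (0.652). Between artesunate and control it had LY96 at -1.80 against -0.44 to 0.23 (0.67), matrix glycoproteins at -0.06 against 0.68 to 1.07 (0.653) and hypoxia genes at -0.97 against 0.11 to 0.64 (0.672).

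In line 2, INHBE changed by 5.64 with TGFβ against 2.44 to 3.41 in the others (0.696), hypoxia genes by 0.58 with artesunate added against -0.10 to 0.15 (0.633), and immediate early genes by 0.52 between artesunate and control against 0.02 to 0.17 (0.706). In line 6, COMP differed from control by 7.68 with artesunate against 3.83 to 4.97 (0.704), and the TLR4 and MD2 list by 0.14 against -0.15 to -0.05 (0.638).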

How the results depend on the processing

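The fit with limma-voom and the averaging of lines were chosen after the data were seen, and the other alternatives before.

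Pairing libraries by line carried most of the gene counts. With no replicate block, 254 genes changed with TGFβ against control, 117 with artesunate against TGFβ and 1848 with artesunate against control, in place of 3538, 2675 and 6252. Without the block the differences between lines stay in the error, which follows from how that fit is built. With fewer lines the counts fell too: in lines 1, 5 and 6 alone they were 15, 16 and 870, in lines 2, 3 and 4 alone 677, 3 and 3036, and with lines 2 and 5 averaged and lines 4 and 6 averaged 1357 and 890 for the first 2 comparisons. Leaving out 1 line gave 1863 (without line 4) to 3445 (without line 1) genes with TGFβ, 2150 being left without line 6, and 1113 (without line 3) to 2333 (without line 2) with artesunate against TGFβ, with 1466 left without line 4 and 1644 without line 5. A minimum of 2-fold left 702, 280 and 1381 genes. The exact Wilcoxon signed-rank test called 0, 0 and 0 genes, since its smallest p with 6 pairs is 0.0312, and 3876, 4236 and 4963 genes had an unadjusted p under 0.05. Array quality weights raised the count with artesunate against TGFβ to 4179, and the cause was not tested. With limma-voom the counts were 3612, 2293 and 6519.

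The correlation across genes between the TGFβ and artesunate effects, -0.043 as reported, was -0.129 with a pseudocount of 0.1, -0.105 with no filter, 0.025 with a mean of at least 5 TPM and -0.162 in lines 1, 5 and 6 alone. In those 3 lines the median artesunate effect was -0.147 on genes raised by TGFβ and -0.178 on genes lowered by it. The causes of these moves were not tested.

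Of the 53 list calls and 467 results of named genes, 0 were marked as reversed under any alternative. Among named genes only those changed in the main fit could be so marked. A reversal of list calls was not looked for with fry or with an estimated correlation. The list calls past the threshold were 45 with no block, 47 and 44 in the separate label series, 51 with averaged lines, 50 with limma-voom, 49 with median-of-ratios scaling, 48 with quantile normalization, 48 of 51 without mitochondrially encoded genes and 47 with fry, and 7 with an estimated correlation. The calls lost in fry were S phase with TGFβ (adjusted p = 0.0713), collagen folding (0.0911), YAP and SRF targets (0.131), interferon-stimulated (0.111) and prostaglandin responsive genes (0.0911) with artesunate against TGFβ, and ribosomal proteins against control (0.0985). With a mean of at least 5 TPM, 45 of 50 stayed past it. Of the named-gene results, 192 stayed on their side of the threshold with no block, 136 and 241 in the separate label series, 362 with averaged lines, 432 with limma-voom, and 388 to 429 with 1 line left out.

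Depth limits the weakly expressed genes most: lines 1, 5 and 6 have a median of 18.89 M reads and lines 2, 3 and 4 of 41.51 M, where a larger share of even counts leaves open whether the reads of a fragment were counted separately. The interaction of the label series with treatment called 0 genes in limma, with 374, 347 and 578 at an unadjusted p under 0.05 in the 3 comparisons.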

Other observations

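The 4 tests of the positional genes and the test of a general loss of the TGFβ response were chosen after the result was seen, and the other tests before.

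For the positional genes of lines 2, 4, 5 and 6 a library batch is argued against, since profiles centred on their treatment correlated at 0.35 or more between lines 2 and 5 and between lines 4 and 6, which cross the label series, and at no more than 0.28 within a series. For line 3 it is argued against as the source of its positional set: its HOX genes overlapped at a Jaccard index of 0.79 with line 5 of the other series and 0.2 with line 4 of its own, and its profile correlated at -0.05 or more with line 5 and -0.23 or less with line 4. Its correlation with line 2 of its own series, 0.2 or more against at most 0.04 with line 5, leaves open a part of the batch in the whole profile, and line 1, alone in its set, was not covered. Single mislabelled libraries are argued against, with 0 out of place. Of 37 HOX genes, those expressed overlapped at 0.79 or more within sets and at most 0.3 between them, so a candidate explanation is different body sites, a hypothesis that the labels, which give heart for all, do not hold, and a whole line under a wrong label stays open.

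The fall of G2 and M phase genes with artesunate is not explained by scaling, since the list median was -1.37 or lower under 2 other scalings, nor by 1 line, since it was -0.97 or lower in each of the 6. A candidate explanation is a slower cell cycle, beside the rise of CDKN1A, and toxicity of the drug at the dose used stays open as well. No viability or cell count was analysed here, and no arm with artesunate alone parts these.

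The rise of contractile genes with TGFβ and their fall with artesunate do not come from the TGFβ libraries that both comparisons use, since with each effect measured in 3 different lines the list rose and fell in 20 of 20 splits. Scaling is argued against too, the median fall being -0.778 or lower under 2 other scalings. A general loss of the TGFβ response is argued against. The median artesunate fall of genes raised by TGFβ was at most 9.15% of their median rise in any of the 20 splits. Single genes went both ways, 168 lowered (71 expected of independent lists) and 167 raised further (132 expected). These counts use the same TGFβ libraries for both effects. They also depend on scaling, the share of rises with artesunate being 65%, or 42.5% with limma-voom. Taken gene by gene over all lines, the loss had quartiles at -42.6% and 34.8%. The contractile list had a median of 0.73 with TGFβ and -0.76 with artesunate. A candidate explanation is an effect on contraction and collagen genes apart from much of the rest of the response, though cell cycle genes also rose and fell, and whether LY96 takes part could not be tested from its RNA level.

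Chance as the source of the gene counts is argued against, though the smallest possible share is 1 in 32 for the swaps and 1 in 100 for the splits. Among the 32 swaps (in limma) of treatment within lines, 1 gave as many genes as the real one, itself, in each comparison, with 3538 genes against a highest other of 179, 2675 against 0 and 6252 against 1648. The swaps that gave 179 and 1648 genes changed 5 of the 6 lines, the mirror of changing 1. Among 100 splits of the libraries 1 gave as many, itself, with highest others of 1393, 258 and 2447.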
